A study of Homo sapiens with 19 samples.

How the data were processed

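The series holds 19 Affymetrix HG_U95Av2 arrays of total RNA from human epidermal keratinocytes, hybridised to oligonucleotide probe sets for known genes. The deposited values are signal intensities on a linear scale, summarised with MAS5 in GCOS per the submitters' processing notes, which give no versions. Detection calls were not used here. The deposited intensities had been scaled to 1 target per array, since their 2% trimmed mean was 500 on the 7 monolayer and 150 on the 11 Skinethic arrays of the groups. Samples were grouped by culture, treatment and time per their titles, or for the monolayer 1 h control per its description, where the title names only the treatment. The series' design text states that each time point had its matched control, so OsM and control arrays of the same culture and time were taken as a set. Within the 8 sets, the arrays' deviations from the group means correlated by -0.03 to 0.33 on average. The array with no group and the monolayer OsM array of 48 h entered the normalization but no comparison. The text files describing each scan were read only for the scan day, the chip lot and the number of scans, as letters.

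Signals were converted to log2 and quantile normalized over the 19 arrays, and values under the 25th percentile (log2 4.58) were set to it, because dim MAS5 signals are noisy and hold no counts. Of 12625 probe sets, 11506 were listed in the probe table, 10961 with 1 gene and 545 with several, and 1119 were unlisted. Probe sets of 1 gene were used, and where a gene had several, as for 1930 genes, the one with the highest mean was kept, which left 8210 genes. Genes above the 40th percentile (log2 5.67) on at least 3 arrays of a fit were tested. No genome build is given with the files, so positions are not stated. A fold against a group at the floor on all its arrays was computed against the floor and is given as a lower bound, and so is one where part of its arrays lay at the floor and the report says so. List medians use the floor in the same way.

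Genes were tested in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a variance trend, two-sided, and Benjamini-Hochberg adjustment at 0.05 over the genes of a comparison. The matched set was a block in all OsM comparisons. A fit with a single OsM term gave the common effect over 8 sets, and a fit with terms for monolayer, Skinethic at 1 and 4 h and Skinethic at 24 h to 7 days gave the 3 separate effects and the difference between late and early. A fit to the 13 arrays of 1, 4 and 24 h gave the difference between the cultures, and the 6 controls of these times gave the untreated comparison. Each time had 1 array per arm, except for 2 OsM arrays at Skinethic 4 h, so times stood in for replicates, and the p-values measure only the spread between these arrays. The number of arrays limits the precision of every value.

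Before the data were examined, 23 gene lists, the comparisons, the main settings and the rule for named genes were fixed. The lists covered JAK-STAT targets, acute phase and complement, immediate early genes, suprabasal keratins, cornified envelope, basal layer, desmosome and adherens junction, activation keratins, antimicrobial and S100 genes, chemokines and cytokines, interferon-stimulated genes, MHC class I, cell cycle, proteases and matrix, cytoskeleton, cholesterol synthesis, heat shock, metallothioneins, ribosomal proteins, and markers of fibroblasts, melanocytes, leukocytes and endothelium. LCN2 is in the acute phase and the antimicrobial list, PI3 in the cornified envelope and the antimicrobial list, and JUNB and MYC are each in 2 lists. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated, and with fry, which asks only whether a list's genes move one way on balance. In a single set, a list's median ratio was ranked among 10000 random lists matched on expression.

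Genes were named by a fixed rule. It took the 10 highest and 10 lowest fold changes among genes that passed with the same sign in every set (no overlap between groups in the untreated comparison, and 5 and 5 with no sign rule for the 2 difference tests), filled up by smallest p where fewer passed. It further took up to 4 members of smallest p per list, the 5 highest and 5 lowest ratios of each 1 and 4 h set, and OSMR, IL6ST, LIFR, STAT3 and SOCS3. LIFR did not pass the filter on dim genes. S100A8 and others named outside the rule were chosen after their values were seen.

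Every comparison was tested on simulated data with 100 genes changed by log2 1 and 100 by log2 2. The share called was 68 and 98% over the 8 sets, 24 and 75% for Skinethic at 24 h to 7 days, 25 and 63% for Skinethic at 1 and 4 h, and 24 and 79% for monolayers. It was 10 and 49% for late minus early, 7 and 36% for Skinethic minus monolayer, and 44 and 84% for the untreated comparison. The simulated noise was normal, with each gene's residual spread, and independent between genes. No floor was set and no shift in low-end level or 3' to 5' ratio was added, so the shares may differ on the real arrays.

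Alternatives fixed in advance were trimmed-mean scaling, cyclic loess, a floor at the 10th percentile, 16 added in place of a floor, no filter or one at the 60th percentile, the mean of a gene's probe sets, no variance trend, no block, each set or control array left out, 1 of the 2 Skinethic 4 h OsM arrays left out or both averaged, a fit to 1 culture, and time as a block. Chosen after seeing the data were 8 alternatives: leaving out the Skinethic 4 h and 48 h sets, keeping only Skinethic sets scanned within 1 day, a floor at the 50th percentile, the low-end level as a covariate, the mean log2 3' to 5' ratio of GAPDH and ACTB as a covariate in the OsM comparisons, scan day as a random block, and, for called lists, cyclic loess and leaving out each set. Also chosen then was the share of the untreated culture difference on the Skinethic arrays outside that comparison, set beside their 3' to 5' ratio, and the correlation of controls by scan day. The median of all genes moved by under 0.1 (log2) under either scaling, and no called list changed direction under them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.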

Results

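Gene expression was measured on 19 oligonucleotide arrays in human epidermal keratinocytes grown with or without oncostatin M (OsM), a cytokine of the interleukin-6 family that signals through gp130, JAK kinases and STAT3. The cells were either subconfluent monolayers or Skinethic cultures, a commercial epidermis reconstructed from stratifying keratinocytes. The monolayer was represented by 3 control arrays, at 1, 4 and 24 h, and by 4 OsM arrays, at 1, 4, 24 and 48 h. Skinethic was represented by 5 control arrays, at 1, 4, 24 and 48 h and 7 days, and by 6 OsM arrays at the same times, with 2 at 4 h. All other combinations of culture, treatment and time had 1 array, so the times of a culture stood in for replicates. The arrays formed 8 matched sets of OsM and control, which left out the monolayer OsM array at 48 h, which has no control of its time among these arrays, and 1 array whose labels conflict. Its title names OsM, Skinethic and 48 h, whereas its source and protocol are those of monolayers and the design text names a replicate only for Skinethic at 4 h, so it was given no group before the data were examined. The same source and protocol are given for 1 of the 2 Skinethic 4 h OsM arrays, which was used as titled because the design text names it. The title of the monolayer 1 h control names only OsM treatment, and its description and protocol name the control.

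Correlations across genes lay between 0.957 and 0.976 among the 7 monolayer arrays, and between 0.788 and 0.877 for a monolayer with a Skinethic array. They were 0.919 to 0.968 among 8 Skinethic arrays, and 0.855 to 0.926 for these with the 3 whose dimmest signals were raised, so that the last range overlapped that between cultures. GAPDH, a housekeeping gene used to gauge RNA integrity, had a log2 ratio of 3' to 5' signal of 1.12 ± 0.25 (SD, n = 5) in Skinethic controls and 0.93 ± 0.38 (n = 6) with OsM. The corresponding ratios of ACTB were 1.26 ± 0.33 and 0.90 ± 0.52. Both ratios were lower with OsM in all 5 Skinethic sets, with log2 differences of -0.12 to -0.50 for GAPDH and -0.09 to -0.81 for ACTB. The monolayer ratios of GAPDH were 0.127 ± 0.169 (n = 3) in controls and 0.131 ± 0.0814 (n = 4) with OsM, and those of ACTB 0.115 ± 0.0873 and 0.061 ± 0.0996, with ACTB lower in all 3 sets (-0.07, -0.14 and -0.05). The 3 arrays with raised dimmest signals were the Skinethic OsM arrays of 4 h and 48 h. Their 25th percentile was 17.1 to 22.9% of the scaling target, against 7.80 to 11.4% on the other 8 Skinethic arrays and 6.78 to 8.20% in monolayers.

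**Figure D1:**
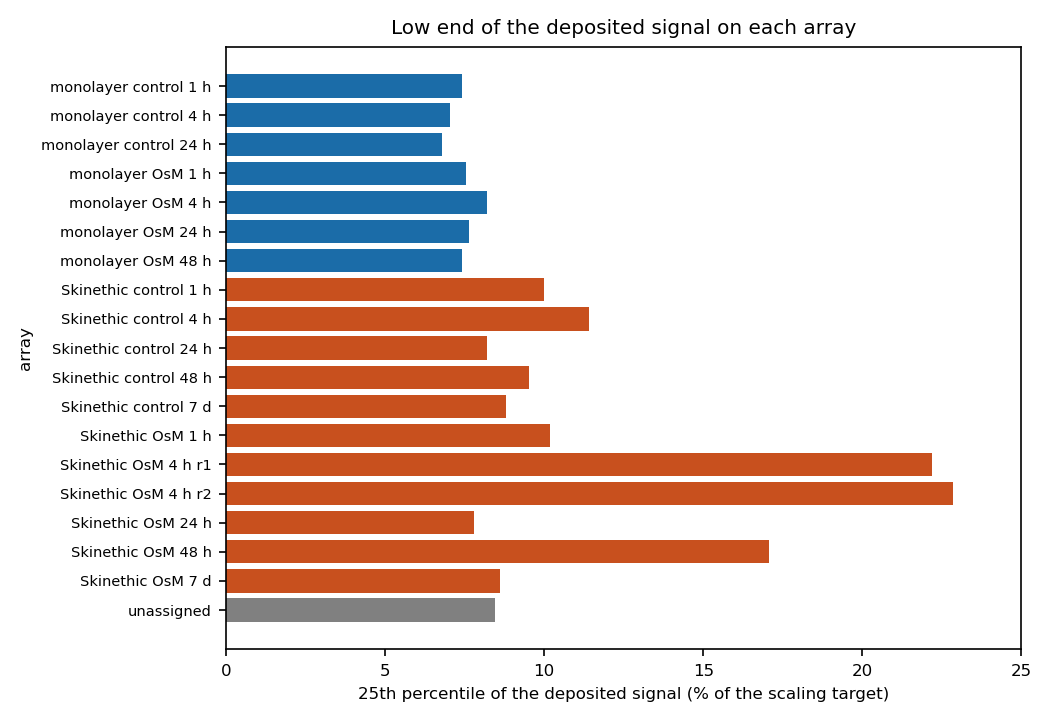
The bars give the 25th percentile of the deposited signal intensity of each of the 19 arrays as a percentage of the array's scaling target. The 3 longest bars, at 17.1 to 22.9%, belong to the Skinethic OsM arrays of 4 h (r1 and r2) and 48 h.

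The untreated cultures were compared at 1, 4 and 24 h (n = 3 arrays per culture) to give the baseline on which OsM acted. Skinethic cultures expressed genes of epidermal differentiation far above monolayers. KRT1, a keratin of suprabasal cells, was 276-fold higher in Skinethic (log2 8.11 ± 0.18, SE), and its partner KRT10 was 26.5-fold higher (log2 4.73 ± 0.16). The barrier protein gene FLG was at least 223-fold higher, the desmosomal cadherin DSC1 at least 418-fold and SLURP1, a protein secreted by differentiated keratinocytes, at least 504-fold. These 3 genes lay at the floor on all 3 monolayer arrays. All 8 tested members of the suprabasal list were higher (median log2 6.52, adjusted p = 1.48e-12), which did not pass with an estimated correlation (adjusted p = 0.171). Of 16 members of the cornified envelope list, 15 were higher and 1 lower (median log2 4.54, adjusted p = 6.77e-13, and adjusted p = 0.227 with an estimated correlation). SPRR1A, a cross-linked envelope precursor, was 39.7-fold higher. Among 11 antimicrobial and S100 genes, 6 were higher and 3 lower (adjusted p = 0.0077, and adjusted p = 0.292 with an estimated correlation). S100A8 and S100A9, which form the antimicrobial calprotectin, differed by log2 6.10 ± 0.27 and 5.33 ± 0.23. The melanocyte markers PMEL and TYRP1 were also higher, by at least log2 3.39 and 3.30 over monolayer levels at or near the floor, with 4 of 5 tested members called (list adjusted p = 0.00545, and adjusted p = 0.228 with an estimated correlation).

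Monolayers in turn expressed genes of simple epithelia, matrix and proliferation above Skinethic cultures. KRT19, a keratin of simple epithelia, was at least 321-fold lower in Skinethic (n = 3 per culture) and the matrix protein gene FN1 at least 126-fold, each with 2 of 3 Skinethic arrays at the floor. The intermediate filament gene VIM was 41.3-fold lower. The matricellular gene THBS1 was at least 93.2-fold lower on the probe set used, with 1 Skinethic array at the floor, while another of its probe sets gave a log2 difference of 0.11. KRT7 likewise had log2 -5.67 on the probe set used and 0.33 on another. Of 43 cell cycle genes, 37 were lower and 40 when adjusted over the list alone (median log2 -1.69, adjusted p = 1.04e-13, and adjusted p = 0.227 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, had log2 -2.94 ± 0.24. Lower members were also called for 10 of 14 basal layer genes, among them the laminin chain LAMB3 (log2 -3.30 ± 0.18, list adjusted p = 2.52e-05). The same held for 15 of 21 cytoskeletal genes, with 1 higher (adjusted p = 3.27e-06), 12 of 21 protease and matrix genes, with 4 higher (adjusted p = 0.0091), and 5 of 8 metallothioneins, with none higher (adjusted p = 0.000327). In the list of activation keratins (adjusted p = 0.00983), KRT16 was higher (log2 4.26 ± 0.21), while KRT7, KRT8, KRT18 and KRT19, which are also keratins of simple epithelia, were lower. Each of these 5 lists had adjusted p = 0.227 with an estimated correlation, and the protease list also missed without the monolayer 24 h control (adjusted p = 0.067). OSMR, which encodes the specific chain of the OsM receptor, was 2.61-fold lower in Skinethic (log2 -1.39 ± 0.24, adjusted p = 0.00191).

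In limma, 1908 of 5710 tested genes differed between the untreated cultures, 918 higher and 990 lower in Skinethic. The 2 groups of arrays did not overlap for 2741 of the 5710 tested genes, where chance gives 10% with 3 arrays against 3. Among the called genes this held for 1884, which in part follows from the call itself. Culture was confounded with scan day and 3' to 5' ratio, so that for a single gene a part of the difference due to these cannot be told apart. Controls of 1 culture scanned on different days correlated at 0.968 to 0.976 in monolayers and 0.938 to 0.955 in Skinethic, against 0.846 to 0.866 between the cultures. On the Skinethic OsM array of 7 days, whose mean 3' to 5' ratio was log2 0.39, the 1908 genes had a median of 90.1% of the difference (quartiles 56.9 to 119%), against 23.0% if it were proportional to that ratio. The scaling target also differed, but after scaling all signals to 1 trimmed mean 1980 genes were called, 1788 of them shared, and all 1882 of the called genes tested there kept their sign. With the low-end level of each array as a covariate, 963 genes were called, 822 of them shared, and OSMR was not among them (adjusted p = 0.0826, with a lowest value of 0.000563 over its alternatives). Its estimate changed little, from log2 -1.39 ± 0.24 to -1.32 ± 0.46, and the call ended with the larger SE. Without the monolayer 1 h control, 1212 genes were called. Of 473 called genes with several probe sets, 109 had 1 or more in the opposite direction.

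**Figure D2:**
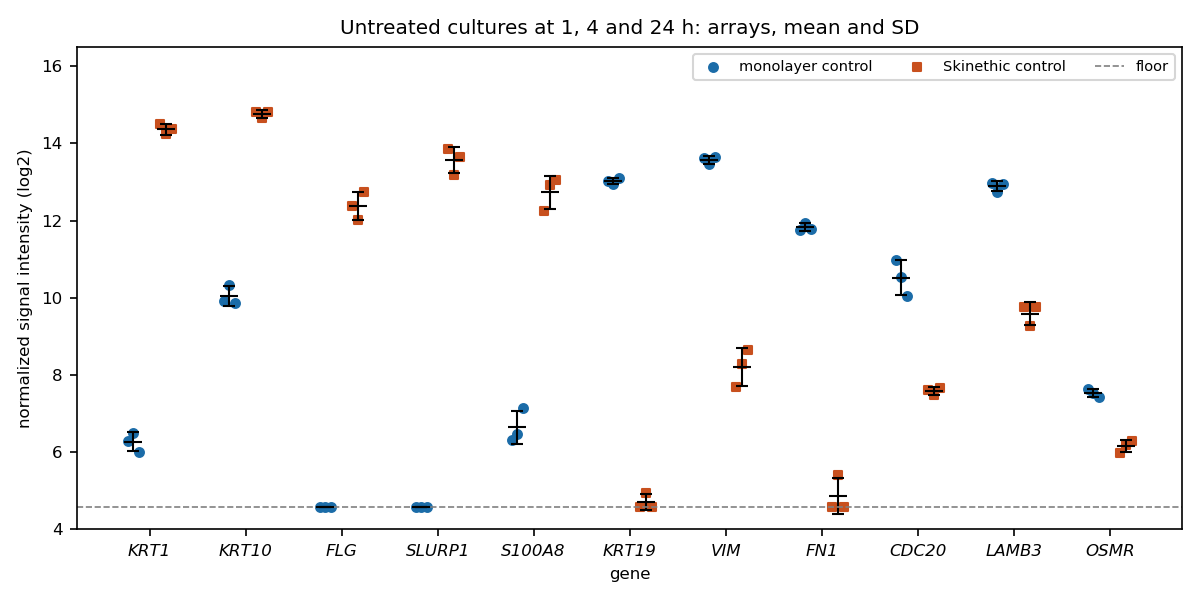
Normalized log2 signal intensity of 11 genes on the 3 monolayer (blue circles) and 3 Skinethic (orange squares) control arrays of 1, 4 and 24 h, with mean and SD (n = 3) in black and the floor as a dashed line. KRT1, KRT10, FLG, SLURP1 and S100A8 are higher on every Skinethic array, and the other 6 genes are higher on every monolayer array.

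The response of stratified cultures to lasting OsM was taken from the Skinethic sets of 24 h, 48 h and 7 days (n = 3 matched sets, values as log2 fold change ± SE). S100A7, which encodes the antimicrobial psoriasin, rose 138-fold (log2 7.10 ± 0.59, adjusted p = 6.99e-05), from a control level of 6.91 ± 0.39 (SD) to 14.0 ± 0.12 on the log2 scale. S100A9, a subunit of calprotectin, rose 6.48-fold (log2 2.70 ± 0.26). LCN2, an iron-sequestering antibacterial lipocalin, rose 5.99-fold (log2 2.58 ± 0.28) and S100P, a calcium-binding protein, 4.27-fold (log2 2.09 ± 0.25). The protease inhibitor gene PI3, known as elafin, rose by log2 1.45 ± 0.25. Of 14 tested antimicrobial and S100 genes, 6 rose and none fell, and 8 rose when adjusted over the list alone (median log2 0.84, adjusted p = 1.1e-14). This list also passed with an estimated correlation (adjusted p = 0.0286).

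STAT3, the transcription factor of the OsM receptor, rose 3.36-fold (log2 1.75 ± 0.24, adjusted p = 0.0016), and a further probe set of the gene gave log2 1.67. It was the only called member among 21 JAK-STAT targets, of which 18 had positive estimates (median log2 0.48, adjusted p = 1.22e-06, and adjusted p = 0.109 with an estimated correlation). The feedback inhibitor SOCS3 (log2 1.33 ± 0.62, all 3 controls at the floor), the receptor chain OSMR (0.98 ± 0.46) and the gp130 gene IL6ST (0.65 ± 0.39) did not pass. Of 12 acute phase and complement genes, LCN2 and the C1 inhibitor gene SERPING1 (log2 1.27 ± 0.28) rose (median log2 0.73, adjusted p = 0.00121, and adjusted p = 0.0977 with an estimated correlation). The vitamin B12-binding protein gene TCN1 rose 10.3-fold (log2 3.37 ± 0.39, adjusted p = 0.000583). HTR3A, a serotonin-gated ion channel subunit, had log2 2.81 ± 0.44 with 2 of 3 controls at the floor, CHI3L2 2.28 ± 0.50 and HSD17B2, an enzyme that inactivates sex steroids, 2.12 ± 0.40. ANXA1 and SPRR2C, both cornified envelope members, rose by log2 1.96 ± 0.30 and 1.96 ± 0.39, whereas the protease inhibitor CST6 of that list fell by 1.39 ± 0.27 on the log2 scale. That list as a whole did not pass (adjusted p = 0.815).

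TNNC1, a calcium-binding troponin, fell at least 10.7-fold (log2 -3.42 ± 0.37, adjusted p = 0.000364), with 2 of 3 OsM arrays at the floor, and TPM1, an actin-binding tropomyosin, fell 5.39-fold (log2 -2.43 ± 0.28) with all 3 of its probe sets lower. The urothelial plaque protein gene UPK1A fell 5.48-fold (log2 -2.45 ± 0.30, adjusted p = 0.000881). IRAG2 (log2 -3.19 ± 0.52), MSMB (-3.00 ± 0.53), FETUB (-2.50 ± 0.38) and the growth factor gene BTC (-2.49 ± 0.47) fell as well. So did AADAC (-2.30 ± 0.44), the carbonic anhydrase CA6 (-2.24 ± 0.41) and HSD11B1 (-2.16 ± 0.38), which regenerates cortisol. Of these, IRAG2, MSMB, BTC and CA6 had 1 or 2 OsM arrays at the floor, so their values are lower bounds in size. KRT2, a keratin of the upper epidermis, fell by 1.68 ± 0.37 on the log2 scale and was the only called member of 8 suprabasal genes (median log2 -0.21, adjusted p = 0.0317, and adjusted p = 0.196 with an estimated correlation). That list missed without the 24 h set (adjusted p = 0.0579). Of 44 cell cycle genes 37 had estimates below 0 and none passed alone (median log2 -0.39, adjusted p = 0.000158, and adjusted p = 0.499 with an estimated correlation).

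Adhesion, matrix and metal-binding genes changed in part. The cadherins CDH3 (log2 1.60 ± 0.27), DSC2 (1.60 ± 0.36) and DSG3 (1.28 ± 0.28) rose, 3 of 14 desmosome and junction genes, in a list that did not pass (adjusted p = 0.124). The collagenase MMP1 (1.63 ± 0.31) and the protease inhibitor SERPINE2 (1.06 ± 0.16) rose and the matricellular SPARC fell (-1.48 ± 0.33) among 22 protease and matrix genes (adjusted p = 0.0323, and adjusted p = 0.272 with an estimated correlation). That list missed without the 7 day set (adjusted p = 0.666). The actin cross-linker ACTN1 rose by log2 1.13 ± 0.14 (adjusted p = 0.00109). Of 8 metallothioneins MT2A rose (1.28 ± 0.21) and MT1X fell (-0.79 ± 0.16), with 6 higher and 1 lower when adjusted over the list alone (median log2 0.51, adjusted p = 0.00121, and adjusted p = 0.304 with an estimated correlation). The remaining lists did not pass: basal layer 0.894, activation keratins 0.826, chemokines 0.0681, interferon-stimulated genes 0.0647, MHC class I 0.549, cytoskeleton 0.403, cholesterol synthesis 0.917, heat shock 0.458, immediate early genes 0.543 and ribosomal proteins 0.0608 (adjusted p). The markers of other cell types did not pass either, with adjusted p of 0.894 for fibroblasts, 0.25 for melanocytes, 0.559 for leukocytes and 0.83 for endothelium.

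In limma 101 of 6548 genes passed at 24 h to 7 days, 50 higher and 51 lower. All had the same sign in the 3 sets, as had 2174 of the tested genes. The count was 22 without the 48 h set (21 shared), 30 without the 7 day set (29 shared), 17 in sets scanned within 1 day (16 shared), 32 without the 4 h and 48 h sets (26 shared) and 67 with the low-end level as a covariate (64 shared). S100A7, TCN1, S100A9, LCN2, S100P, TNNC1, UPK1A, TPM1 and ACTN1 passed under 19 of 20 alternatives, the exception being the 3' to 5' ratio as a covariate. STAT3 missed there and within 1 scan day (adjusted p = 0.0516, with a lowest value of 0.000105 and a highest of 1.00 over its alternatives). Without the 48 h set, 22 of the 34 named genes that passed missed the threshold, with adjusted p of 0.0624 to 0.44. They were HTR3A, CHI3L2, SPRR2C, PI3, SERPING1, CDH3, DSG3, DSC2, SERPINE2, MMP1, MT2A, IRAG2, MSMB, FETUB, BTC, AADAC, CA6, HSD11B1, CST6, KRT2, SPARC and MT1X. Without the 7 day set 20 missed (adjusted p of 0.0603 to 0.423), namely HSD17B2 and all of those 22 but HTR3A, CDH3 and SERPINE2. Without the 24 h set 8 missed (adjusted p of 0.0511 to 0.136), namely CHI3L2, HSD17B2, SERPING1, CDH3, DSG3, MT2A, CA6 and MT1X.

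The 3' to 5' ratio moved with OsM in these 3 sets, the log2 differences being -0.16, -0.50 and -0.38 for GAPDH and -0.22, -0.81 and -0.73 for ACTB at 24 h, 48 h and 7 days. With this ratio as a covariate, limma called 0 genes (smallest adjusted p = 1.00), and 170 had an unadjusted p under 0.05, fewer than the 327 expected by chance. The SE of the 101 genes grew 2.32-fold in the median, since the ratio and late OsM go together, while their estimates were 74.1% of those before and 96 kept their sign. S100A7 then had log2 5.77 ± 1.32, S100A9 2.54 ± 0.61, LCN2 2.37 ± 0.66, STAT3 1.12 ± 0.54 and TNNC1 -2.31 ± 0.80. BTC (-0.13 ± 0.85), MSMB (-0.34 ± 0.95) and SERPING1 (0.01 ± 0.54) were near 0 and SPARC changed sign (0.11 ± 0.61). KRT2 (-0.66 ± 0.82), AADAC (-0.67 ± 0.90), SPRR2C (0.58 ± 0.82) and MT1X (-0.33 ± 0.35) also had estimates smaller than their SE. MMP1 (0.70 ± 0.685) and PI3 (0.68 ± 0.53) shrank as well. Late OsM and RNA quality are not separated for these genes, nor by a passed test for any other single gene. The antimicrobial and S100 list was called with the covariate by camera at the preset correlation (median log2 0.91, adjusted p = 1.19e-09). The other 6 late lists missed (adjusted p of 0.127 to 0.404). No list was tested with an estimated correlation and this covariate together. In the 24 h set, where the ratio differed least, the log2 ratio was 6.80 for S100A7, 2.36 for S100A9, 2.07 for LCN2 and 1.29 for STAT3.

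**Figure D3:**
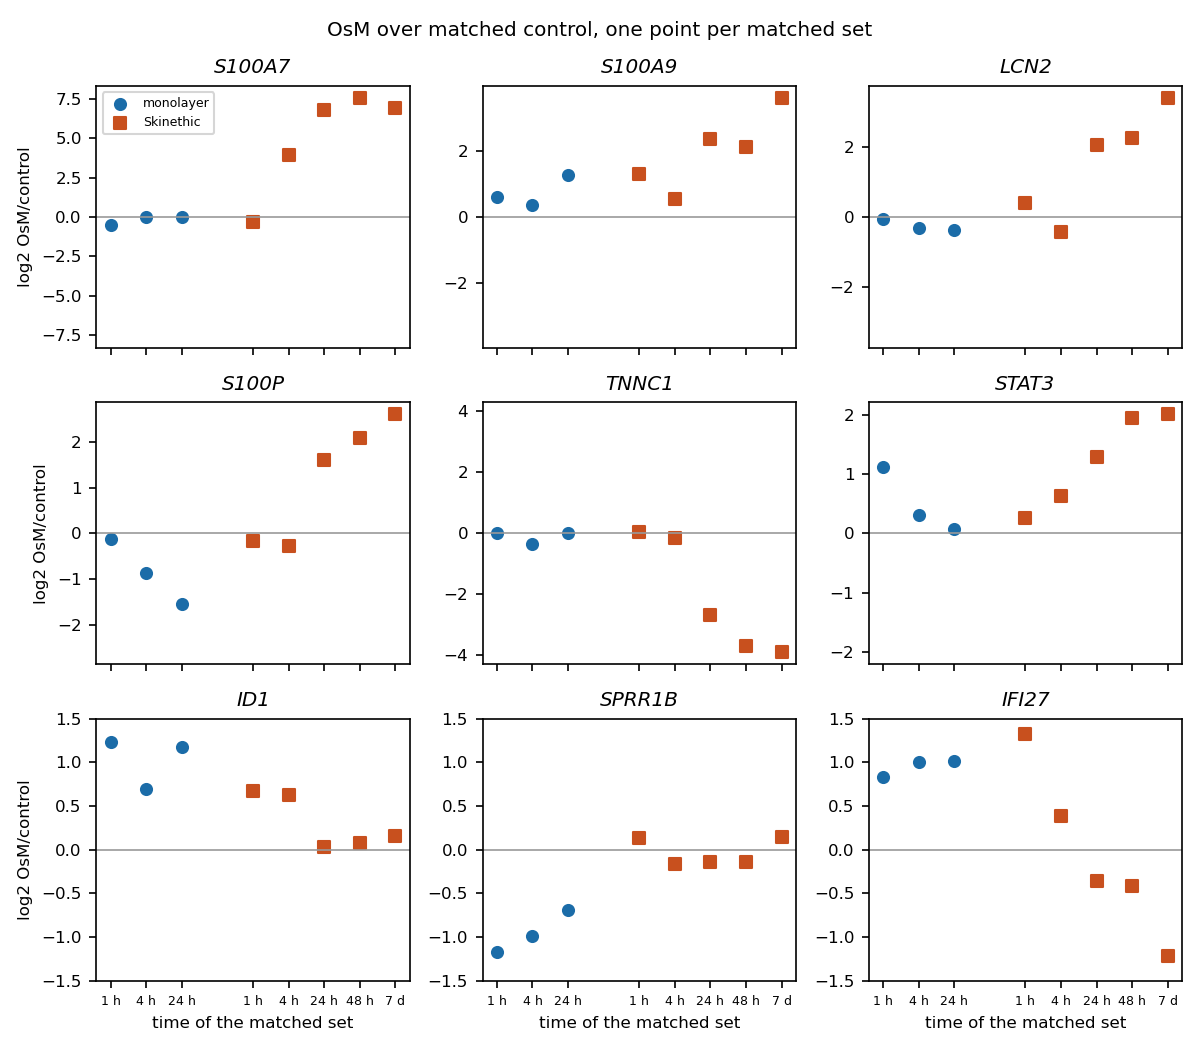
Each point is the log2 ratio of OsM to matched control in 1 of the 8 matched sets for 9 genes, with monolayer sets as blue circles, Skinethic sets as orange squares and 2 OsM arrays averaged at Skinethic 4 h. S100A7, S100A9, LCN2, S100P and STAT3 lie above 0 and TNNC1 below 0 in the Skinethic sets of 24 h, 48 h and 7 days, whereas ID1 is above and SPRR1B below 0 in all 3 monolayer sets.

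The early response of stratified cultures was taken from the Skinethic sets of 1 and 4 h (n = 2 matched sets, 2 controls and 3 OsM arrays), in which no gene passed. The interferon-stimulated list was higher, with 22 of 27 members above 0 (median log2 0.58, adjusted p = 1.06e-05, and adjusted p = 0.519 with an estimated correlation), and 3 members passed when adjusted over the list alone. Its median was 1.15 at 1 h and 0.21 at 4 h, and without the 1 h set the list missed (adjusted p = 0.296). Melanocyte markers were also higher in the 1 h set, with log2 ratios of 1.02 for PMEL, 0.89 for MLANA and 0.83 for TYRP1, but -0.39 for TYR. At 4 h the ratios of these genes were 0.52, 1.29, -0.59 and 1.03, and the melanocyte list was not called in the early comparison. The antiviral membrane protein gene IFITM3 had log2 0.77 ± 0.14 (adjusted p = 0.144) and its relative IFITM2 0.95 ± 0.23 (adjusted p = 0.186). The BMP target ID1 had log2 0.65 ± 0.13, the proto-oncogene MYC 1.57 ± 0.37 and the monocyte attractant CCL2 1.87 ± 0.50. S100A7 had at least 2.11 ± 0.67, which rested on the 4 h set, where its control was at the floor, the log2 ratio at 1 h being -0.29. On the lower side were NT5E, an ectonucleotidase (log2 -2.38 ± 0.36, adjusted p = 0.0787), the peptide transporter TAP2 (-2.35 ± 0.39) and KRT18 (-0.95 ± 0.20). Values of STAT3 (0.47 ± 0.27) and IL6ST (0.24 ± 0.45) were within 2 SE of 0. So was that of OSMR (-0.14 ± 0.52), which was positive after trimmed-mean scaling (0.23) or cyclic loess (0.14). In limma 0 of 6548 genes passed, and 842 had an unadjusted p under 0.05, against 327 expected by chance. Without the 1 h set 356 genes passed, all from the 4 h set, whose OsM arrays had the raised low end, and without the 4 h set 1 passed. All 8 metallothioneins had estimates above 0 (median log2 0.37, adjusted p = 0.00593, and adjusted p = 0.519 with an estimated correlation), but the median was -0.02 without the 4 h set (adjusted p = 0.771).

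Single early sets, which have no replicate check, gave larger ratios. In Skinethic at 1 h, the acute phase gene SAA1 had a log2 ratio of 3.12 and IGFBP2 was at least 20.7-fold higher with OsM, its control being at the floor. At 4 h S100A7 was at least 15.1-fold higher and the RNA-binding protein gene ELAVL2 had a log2 level of 9.34 against 4.73, near the floor. NME4 had 5.05, near the floor, against 8.84 in the control, and both OsM arrays of this set had the raised low end. In monolayers at 1 h SOCS3 was at least 22.6-fold higher, with the control at the floor, and the mRNA decay factor ZFP36 5.58-fold higher. At 4 h in monolayers the stress transcription factor DDIT3 was at least 17.9-fold lower, with the OsM array at the floor. The immediate early list had a median log2 ratio of 1.16 in the monolayer 1 h set, with 18 of 20 members above 0, and this lay at the 100th percentile of 10000 random lists of matched expression. In the Skinethic 1 h set its median was 0.05, at percentile 66.8.

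Whether the late and early responses of Skinethic cultures differed was tested as a contrast. The late effect was higher than the early one for HSD17B2 (log2 difference 3.57 ± 0.60), TAP2 (3.22 ± 0.53), NT5E (2.91 ± 0.48), LCN2 (2.65 ± 0.42) and S100P (2.32 ± 0.38), and lower for TNNC1 (-3.35 ± 0.55). S100A7 differed by 4.99 ± 0.89 and did not pass (adjusted p = 0.0555). The antimicrobial and S100 list was higher late, with 11 of 14 members above 0 (median 0.95, adjusted p = 4.65e-08, and adjusted p = 0.128 with an estimated correlation). Interferon-stimulated genes were lower late, with 4 of 27 members above 0 (median -0.65, adjusted p = 1.77e-07, and adjusted p = 0.498 with an estimated correlation). IFI27, an interferon-induced mitochondrial protein gene, differed by -1.46 ± 0.28 (adjusted p = 0.0885). JAK-STAT targets (median 0.41, adjusted p = 0.0478), cell cycle genes (-0.32, adjusted p = 0.0478) and protease and matrix genes (0.43, adjusted p = 0.049) passed narrowly. With an estimated correlation these 3 lists had adjusted p = 0.498, 0.672 and 0.498.

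In limma 6 of 6548 genes differed between late and early effects. All 6 missed without the 4 h set (adjusted p of 0.196 to 0.271), the 24 h set (0.0574 to 0.117), the 48 h set (0.182 to 0.198) or the 7 day set (0.166), and the counts were then 3, 0, 0 and 0, against 43 without the 1 h set. All 6 missed as well with 1 of the 2 Skinethic 4 h OsM arrays left out (0.0899 to 0.111) or both averaged (0.0733 to 0.0856). So they did with the floor at the 10th percentile (0.0867 to 0.172), without a filter (0.0743 to 0.204), without a variance trend (0.0599 to 0.325) and with the low-end covariate (0.0625 to 0.0817), where the estimates were 95.7% of those before in the median and the SE 1.01 times as large. The 6 also missed within 1 scan day (adjusted p of 0.189 to 0.293) and without the 4 h and 48 h sets, which left only the 1 h set early. With the 3' to 5' ratio as a covariate limma called 0 genes, and 478 had an unadjusted p under 0.05, against 327 expected by chance. The 6 genes then had adjusted p of 0.312 to 0.524. Their estimates were then 94.2% of those before in the median and the SE 1.31 times as large. The estimates of HSD17B2 and NT5E grew (to 4.19 and 3.05). Those of TAP2, LCN2, S100P and TNNC1 shrank (to 2.855, 2.53, 2.16 and -2.69), so their calls ended with a larger SE and a smaller estimate. That covariate also ended the calls of JAK-STAT targets (adjusted p = 0.568), cell cycle genes (0.242) and protease and matrix genes (0.242). JAK-STAT targets missed without the 1 h set (adjusted p = 0.486), the 48 h set (0.137) or the 7 day set (0.193), and cell cycle genes without the same sets (0.486, 0.137 and 0.249). Protease and matrix genes missed without the 1 h (0.143), 4 h (0.31), 48 h (0.0554) or 7 day set (0.392).

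The response of monolayers was taken from the sets of 1, 4 and 24 h (n = 3 matched sets). SERPINB3, a serpin known as squamous cell carcinoma antigen, rose at least 3.28-fold (log2 1.71 ± 0.19, adjusted p = 0.00175) from control levels at or near the floor, and ID1, an inhibitor of differentiation and BMP target, rose 2.05-fold (log2 1.03 ± 0.12, adjusted p = 0.00175). The cornified envelope precursors SPRR1B and SPRR1A fell 1.93-fold (log2 -0.95 ± 0.12, adjusted p = 0.00413) and 1.55-fold (log2 -0.63 ± 0.10, adjusted p = 0.0494). Of 16 cornified envelope genes these 2 fell, and 5 fell when adjusted over the list alone (median log2 -0.23, adjusted p = 0.000245, and adjusted p = 0.404 with an estimated correlation). Interferon-stimulated genes were higher, with 25 of 27 members above 0 and 7 passing when adjusted over the list alone (median log2 0.61, adjusted p = 7.22e-14, and adjusted p = 0.404 with an estimated correlation). IFIT3 had log2 1.96 ± 0.50, IFI27 0.95 ± 0.18 and IFITM1 0.76 ± 0.15, none passing over all genes. Of 12 MHC class I and antigen processing genes 11 had positive estimates (median log2 0.30, adjusted p = 0.000245, and adjusted p = 0.404 with an estimated correlation). JAK-STAT targets (median 0.33, adjusted p = 0.000245) and immediate early genes (0.28, adjusted p = 0.00046) were higher and junction genes lower (-0.25, adjusted p = 0.0455). With an estimated correlation all 3 had adjusted p = 0.404. SOCS3 (log2 2.13 ± 0.62), JUNB (1.13 ± 0.27), STAT3 (0.50 ± 0.24), OSMR (0.53 ± 0.46) and IL6ST (-0.30 ± 0.39) did not pass.

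In limma 4 of 6548 genes passed in monolayers, all with the same sign in the 3 sets, as had 1724 of the tested genes. An unadjusted p under 0.05 was found for 295, fewer than the 327 expected by chance. All 4 missed without a filter on dim genes (adjusted p of 0.05 to 0.0632) or without a variance trend (0.119 to 1), and 3 of them with trimmed-mean scaling (0.163 to 0.461). The count was 2 without the 4 h set and 7 without the 24 h set. SPRR1B missed without the 1 h (adjusted p = 0.0896) or 4 h set (0.0603), and SPRR1A without any 1 of the 3 sets (0.27, 0.265 and 0.0881). With the 3' to 5' ratio as a covariate 4 genes were called, 3 of them shared, SPRR1A not being among them (log2 -0.64 ± 0.11, the SE having grown from 0.10, adjusted p = 0.0982, with 0.0321 to 1 over its alternatives), and junction genes missed (0.0801). JAK-STAT targets missed without the 1 h set (adjusted p = 0.153), immediate early genes likewise (adjusted p = 0.964, the median changing sign), and junction genes missed without the 24 h set (adjusted p = 0.533). At 4 and 24 h the OsM and control arrays were scanned on different days, so treatment and day cannot be told apart there. In the 1 h set, scanned on 1 day, the log2 ratios were 1.57 for SERPINB3, 1.24 for ID1, -1.18 for SPRR1B and -0.60 for SPRR1A. All 4 genes missed in a fit to monolayer arrays only (adjusted p = 0.325, 0.105, 0.149 and 0.416), and with the floor at the 50th percentile SERPINB3 had log2 0.03 (adjusted p = 1, with a lowest value of 0.00114 over its alternatives).

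**Figure D4:**
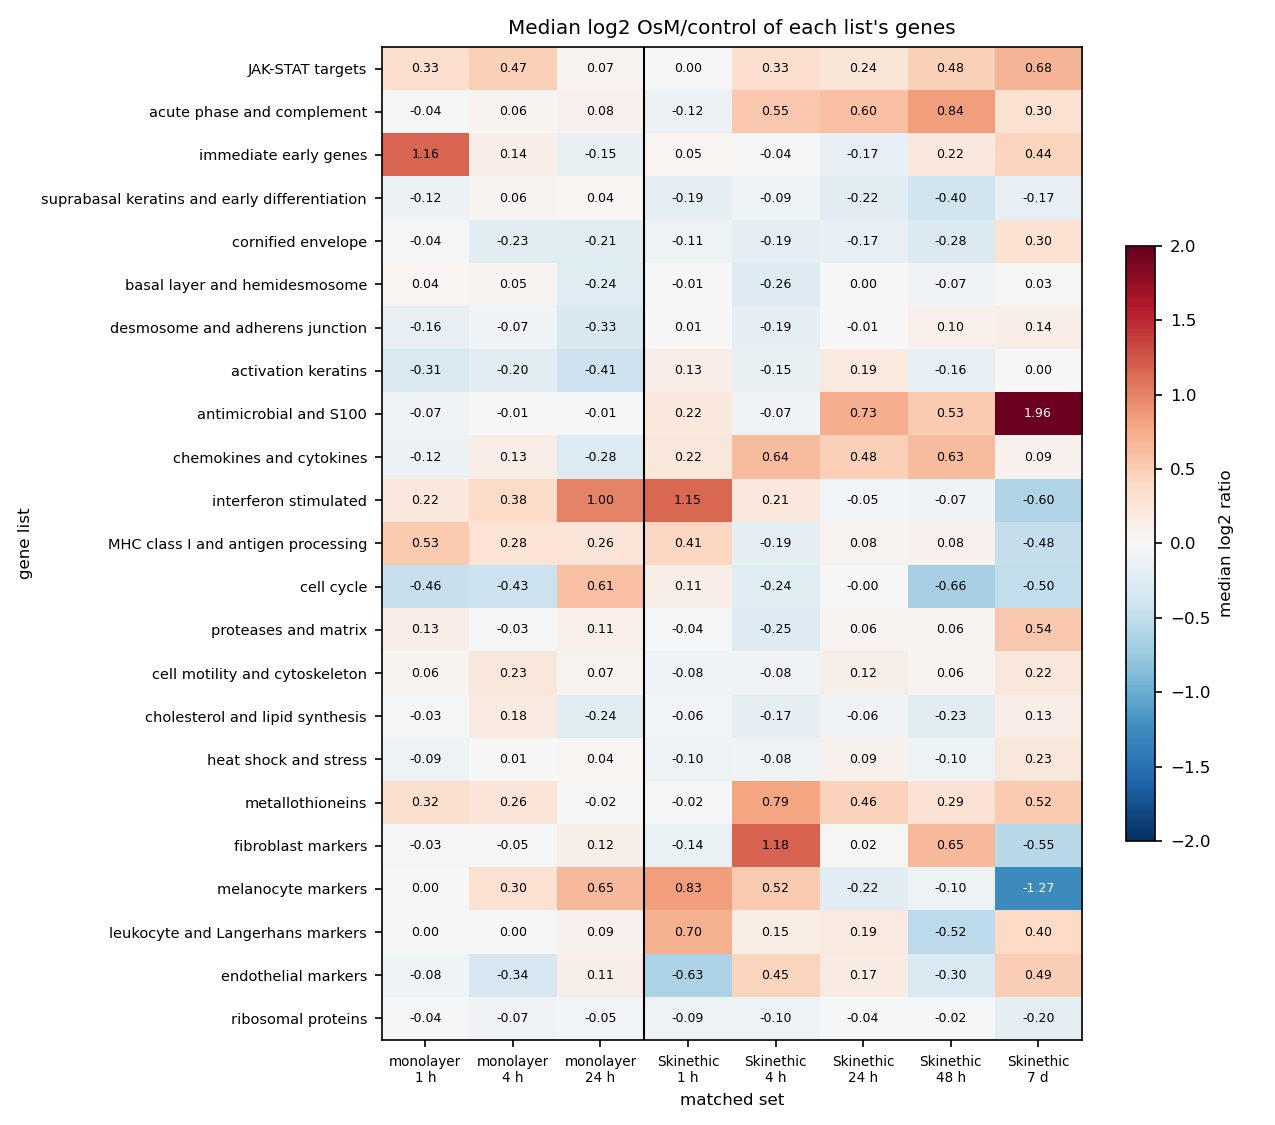
Median log2 ratio of OsM to matched control for the tested genes of 23 lists in each of the 8 matched sets, as colour and number, red above and blue below 0, with 1 array per arm except at Skinethic 4 h. Antimicrobial and S100 genes have medians of 0.73, 0.53 and 1.96 in the Skinethic sets of 24 h, 48 h and 7 days, and interferon-stimulated genes 1.00 in the monolayer 24 h and 1.15 in the Skinethic 1 h set.

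Whether the cultures differed in their response was tested at 1, 4 and 24 h (n = 3 matched sets per culture). No gene passed. SPRR1B had the smallest unadjusted p among higher genes, with an OsM effect higher in Skinethic by log2 0.88 ± 0.17 (adjusted p = 0.764), followed by SPRR1A (0.62 ± 0.15). ERP29, a chaperone of the endoplasmic reticulum, differed by -1.39 ± 0.26 and SERPINB3 by -1.37 ± 0.30, so neither the SERPINB3 nor the SPRR1 response was shown to differ between the cultures. Antimicrobial and S100 genes had a higher OsM effect in Skinethic, with 11 of 13 members above 0 (median 0.57, adjusted p = 0.000302, and adjusted p = 0.541 with an estimated correlation). Chemokines and cytokines also did (median 0.47, adjusted p = 0.0273), whereas the effect was lower for suprabasal genes (-0.36, adjusted p = 0.0273) and MHC class I genes (-0.34, adjusted p = 0.0349). At 1, 4 and 24 h the suprabasal median was -0.19, -0.09 and -0.22 in Skinethic against -0.12, 0.06 and 0.04 in monolayers, and the MHC class I median 0.41, -0.19 and 0.08 against 0.53, 0.28 and 0.26. With an estimated correlation these 3 lists had adjusted p = 0.324, 0.324 and 0.541. All 4 missed without the Skinethic 24 h set (adjusted p = 0.114 for each). Chemokines also missed without the monolayer 24 h set (0.0538), suprabasal genes without the Skinethic 1 h (0.121) or 4 h set (0.0521), and MHC class I genes without the monolayer 1 h (0.131), monolayer 24 h (0.0514) or Skinethic 4 h set (0.426). With the 3' to 5' ratio as a covariate these last 3 lists missed (adjusted p = 0.12, 0.118 and 0.681). In limma 0 of 6339 genes passed, and 328 had an unadjusted p under 0.05, against 317 expected by chance.

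A response common to both cultures and all times was sought over the 8 matched sets (n = 8). No gene passed, and those of smallest p included the following. S100A9 had log2 1.49 ± 0.28, the mesothelial antigen MSLN 1.31 ± 0.23, CCL2 1.30 ± 0.26, LILRB3 1.17 ± 0.21, S100A8 0.93 ± 0.18, DSG3 0.92 ± 0.18 and the interferon-gamma receptor chain IFNGR1 0.67 ± 0.13, with adjusted p of 0.107 to 0.125 and the same sign in every set. That sign is no separate support, since the rule that filled up the named genes asked for it, and 97 of the 6548 tested genes had it. On the lower side were CST6 (-0.92 ± 0.19) and the cytokine IL18 (-0.71 ± 0.14), both with adjusted p = 0.125, IL18 being above 0 in 1 set. STAT3 had log2 0.94 ± 0.21 (adjusted p = 0.165), SOCS3 1.37 ± 0.39, OSMR 0.51 ± 0.28 and IL6ST 0.19 ± 0.25. JAK-STAT targets were higher, all 21 with estimates above 0 (median log2 0.20, adjusted p = 2.93e-07), as were all 8 metallothioneins (0.31, adjusted p = 3.08e-05) and 9 of 12 acute phase genes (0.53, adjusted p = 0.00321). With an estimated correlation each of these 3 lists had adjusted p = 0.155. Interferon-stimulated genes (median 0.25, adjusted p = 0.000107), antimicrobial and S100 genes (0.27, adjusted p = 0.000247) and immediate early genes (0.27, adjusted p = 0.0159) were higher as well. With an estimated correlation these had adjusted p = 0.402, 0.381 and 0.408. Cell cycle genes (median -0.18, adjusted p = 0.00324), ribosomal proteins (-0.08, adjusted p = 0.00324) and suprabasal genes (-0.29, adjusted p = 0.0476) were lower, with adjusted p = 0.486, 0.333 and 0.333 with an estimated correlation. Suprabasal genes missed without any 1 of the 5 Skinethic sets (adjusted p of 0.073 to 0.152), and immediate early genes without the monolayer 1 h (0.239) or Skinethic 7 day set (0.0615). With the 3' to 5' ratio as a covariate acute phase (0.755), suprabasal (0.938), cell cycle (0.938) and antimicrobial genes (0.906, the median changing sign) missed. In limma 0 of 6548 genes passed, and 674 had an unadjusted p under 0.05, against 327 expected by chance. After trimmed-mean scaling 7 genes passed.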

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

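The tests on list medians in the sets without a raised low end and on marker lists were planned before their results were seen, while the settings without the 4 h and 48 h sets and with the 3' to 5' ratio as a covariate were chosen after the data were seen. The leukocyte test applied a condition beyond its planned rule, given below. The late OsM effect in Skinethic differed from the early one, by a test of the difference itself, for 6 genes, which all missed with that covariate (adjusted p of 0.312 to 0.524). The log2 differences were 3.57 for HSD17B2, 3.22 for TAP2, 2.91 for NT5E, 2.65 for LCN2, 2.32 for S100P and -3.35 for TNNC1. TAP2 and NT5E owe much of their difference to low early values, with early estimates of -2.35 and -2.38 that did not pass. HSD17B2 owes a part of its difference to them, with log2 ratios of -1.056 at 1 h and -1.755 at 4 h. Among lists, the median differences were 0.95 for antimicrobial and S100 genes, 0.41 for JAK-STAT targets, 0.43 for protease and matrix genes, -0.65 for interferon-stimulated genes and -0.32 for cell cycle genes, none of which passed with an estimated correlation (adjusted p of 0.128 to 0.672). Between the cultures at 1, 4 and 24 h, the Skinethic minus monolayer differences of the OsM effect had list medians of 0.57 for antimicrobial and S100 genes, 0.47 for chemokines and cytokines, -0.36 for suprabasal genes and -0.34 for MHC class I genes, again none passing with an estimated correlation (adjusted p of 0.324 to 0.541). These 4 lists all missed without the Skinethic 24 h set (adjusted p = 0.114 for each), whose antimicrobial median was 0.73.

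The monolayer OsM array of 48 h, which entered no comparison, lay above all 3 monolayer controls for 9 of the 10 higher genes that the rule names in monolayers. Against the control mean it was higher by at least log2 3.54 for SERPINB3, whose controls were at or near the floor, and by 1.37 for ID1, 1.15 for MT1X, 1.17 for IFI27, 1.25 for IFITM1 and 0.91 for the lysosomal protease gene CTSL. FGFR3, FAT1 and JUNB were higher by 1.34, 0.47 and 0.91. These genes were chosen as higher against the same 3 controls, so that part of the agreement is built in, and 28.2% of all tested genes lay above the 3 controls on this array. The controls were of earlier times and other scan days, so time, day and OsM cannot be told apart in this array.

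Antimicrobial and S100 genes rose in Skinethic at 24 h to 7 days. In the 24 h and 7 day sets, scanned within 1 day each and without a raised low end, the list median lay at the 100th percentile of random lists, which argues against low-end signal or scan day of the 48 h OsM array as the whole cause. RNA from leukocytes, which also carry S100A8 and S100A9, was tested with a list of leukocyte markers, whose late median was 0.18 with 7 of 13 members above 0 and an SD of 0.73. The planned rule took a low leukocyte median as an argument against admixture, and its bound was met. A condition added to that rule was not met, since the antimicrobial median (0.84) did not exceed the leukocyte median by more than that SD. Members going both ways therefore leave an admixture open, in a culture described as reconstructed from keratinocytes. Log2 levels under OsM were 7.05 for CD74 (control 7.85) and 6.76 for HLA-DRA (control 6.57), beside 14.5 for S100A8 (control 12.9). RNA quality also stays open, since the 3' to 5' ratio was lower with OsM in these sets. With it as a covariate no single gene passed, although the list median was 0.91 (camera at the preset correlation, adjusted p = 1.19e-09). An estimated correlation, which had raised the list's p without the covariate, was not used there. An OsM effect on keratinocytes may be the cause beside admixture and RNA quality.

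Interferon-stimulated genes were higher early than late after OsM in Skinethic, which did not pass with an estimated correlation (adjusted p = 0.498). Without the 4 h and 48 h sets, whose OsM arrays had the raised low end, the list median of the difference was -1.14 (quartiles -2.17 to -0.72). A difference thus remained without those arrays, which argues against their low-end signal as the whole cause. The early side was then the 1 h set alone, whose list median was above that at 4 h, so the larger size follows from leaving out 4 h. Among the 20 members above the median level of tested genes it was -0.68 (quartiles -1.36 to -0.26), which argues against noise of dim genes. The early rise rests largely on the 1 h set, with 1 array per arm and a median of 1.15 (without it the early list had adjusted p = 0.296), but the difference passed without that set (median -0.50, adjusted p = 0.0389), and the median was 0.21 at 4 h and -0.60 at 7 days. An OsM effect that changes with time may be the cause, and so may handling of single cultures, or low-end signal at 4 h together with the 1 h culture, as each set has 1 control. Melanocyte markers shifted between single sets, and that shift itself was not tested. As a list they were tested with the others, and were not called early or in late minus early. At 1 h and 7 days the log2 ratios were 1.02 and -1.71 for PMEL, 0.89 and -1.38 for MLANA and 0.83 and -1.27 for TYRP1. Those of TYR were -0.39 and -0.83.

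Other splits of the arrays were compared for the gene counts. For late Skinethic, 101 genes were called by the real split and at most 2 by the 9 others. The monolayer counts were 4 and at most 2, those of the untreated cultures 1908 and at most 0, and for the difference between the cultures' responses the real and all other splits called 0. In these 4 comparisons 10 splits are too few for a share under 0.05. The other late Skinethic and monolayer splits took no account of the matched sets. Most placed the OsM and control array of a set in the same group, which left fewer sets to carry the contrast. The rest had OsM and control arrays in each group, and the other untreated splits had each culture in each group. A real difference then adds to the spread within groups. Low counts in other splits were thus in part built in and decide nothing. Over the 8 sets the real count was 0, so that comparing it with other splits decides nothing. The highest count among those splits was 60. They reassigned OsM over all arrays and so broke up the matched pairs, and the cause of that count was not tested.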

How the results depend on the processing

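The covariates for the low-end level and the 3' to 5' ratio, the floor at the 50th percentile, the 1-day sets, leaving out the 4 h and 48 h Skinethic sets, and loess and leave-one-out for lists were tests chosen after the data were seen. Of 679 values of the 34 named late genes, 488 stayed past the threshold, 190 missed it with the direction kept and 1 changed sign, SPARC with the 3' to 5' covariate (0.11). The first 2 numbers were 45 and 35 of 80 for the 4 monolayer genes, 40 and 92 of 132 for the 6 late minus early genes, and 1394 and 49 of 1443 for 89 genes of the untreated cultures. Among all called genes, 96 of 101 late ones kept their sign with the 3' to 5' covariate, and of the untreated ones 1888 of 1908 with the low-end covariate, 1867 of 1876 with the mean of probe sets and 1792 of 1793 with the floor at the 50th percentile. Where a count moved, the cause was not tested, except that fewer arrays lower precision and that the 3' to 5' ratio goes with late OsM, which raised the SE of late calls 2.32-fold in the median. Over the 8 sets, 7 genes were called after trimmed-mean scaling. The late count was 177 with cyclic loess, 40 without a filter, 29 without a variance trend, 22 to 77 with 1 set left out, 32 without the 4 h and 48 h sets, 17 in 1-day sets, 67 with the low-end covariate and 0 with the 3' to 5' covariate. The early count was 2 with the mean of probe sets, 5 without a filter, 261 without the block, 1 to 356 with 1 set left out and 2 without the 4 h and 48 h sets. The monolayer count was 2 with trimmed-mean scaling or no block, 0 without a filter or without a trend, 1 with its own culture only or without the 4 h and 48 h sets, and 2 to 7 with 1 set left out. The late minus early count was 0 with the floor at the 10th percentile, without a trend, with 1 of the 2 4 h arrays left out or both averaged, in 1-day sets and with the 3' to 5' covariate. It was 11 with the floor at the 50th percentile, 1 without a filter, 457 without the block, 0 to 43 with 1 set left out, and 2 with its own culture only, without the 4 h and 48 h sets or with the low-end covariate. The count of the untreated cultures was 1212 to 1862 with 1 array left out and 963 with the low-end covariate. Against 43 list calls, there was 1 with an estimated correlation and there were 23 with fry. Among named values, the other changes of sign concerned ones that had not passed and 3 lists. Without 1 set IL6ST ranged from -0.0056 to 0.36 over the 8 sets, -0.066 to 0.66 early, -0.69 to 0.053 in monolayers and -0.099 (without 48 h; -0.0071 without 4 h) to 0.77 for late minus early. It was -0.00099 over the 8 sets and -0.12 early with the low-end covariate, -0.27, -0.026 and -0.0087 over the 8 sets, early and late with the 3' to 5' covariate, and for late minus early -0.092 without the block, -0.51 without the 4 h and 48 h sets and -0.28 in 1-day sets. Early OSMR was 0.23 with trimmed-mean scaling, 0.14 with loess, 0.0038 with the mean of probe sets, 0.15 with the floor at the 50th percentile, 0.22 without the 4 h and 48 h sets and -0.41 to 0.22 with 1 set left out. Early STAT3 was -0.15 with the mean of probe sets and -0.028 without the block, which also gave -0.47 for IFITM3, -0.19 for ID1 and 0.55 for the late minus early value of IFI27. SERPINB3 was 0.31 for Skinethic minus monolayer with the floor at the 50th percentile, since its monolayer controls lay near the floor. STAT3 ranged from -0.021 to 0.54 for Skinethic minus monolayer and from -0.15 (-0.040 without the monolayer 1 h control) to 0.55 untreated. The early metallothionein list had adjusted p = 0.797 without the 4 h and 48 h sets and 0.000771 to 0.771 with 1 set left out, the monolayer immediate early list 1.4e-07 to 0.964, and the antimicrobial list over the 8 sets 0.906 with the 3' to 5' covariate. A scan-day block could not be fitted for the untreated cultures, since the 6 controls span 5 days and 1 day holds over 1 array. Time as a block and the other alternatives of each comparison kept its count within 1.5 times. Signal over background limits the dim genes, as the floors show.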

Other observations

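Leaving out single sets was chosen before the data were examined, and the genes named here were chosen after their values were seen. Besides the genes named by rule, late Skinethic calls included the oxysterol enzyme CH25H (log2 1.94 ± 0.39, n = 3 sets), the IL-4 receptor chain IL4R (1.70 ± 0.23), NAMPT (1.69 ± 0.31) and the inflammatory caspase CASP4 (1.28 ± 0.17). The interferon-gamma receptor chain IFNGR1 (0.91 ± 0.20) and S100A8 (1.62 ± 0.21) rose as well. BLMH, a hydrolase that processes filaggrin, fell 3.87-fold (log2 -1.95 ± 0.21, adjusted p = 0.000364), and the cyclin CCND1 (-1.02 ± 0.16), the BMP target ID3 (-1.48 ± 0.28) and the protease CTSH (-1.27 ± 0.19) fell. With the 3' to 5' ratio as a covariate all of these missed. Some estimates changed little or moderately while the SE grew, with log2 2.32 ± 0.51 for IL4R, 1.80 ± 0.74 for NAMPT, 1.71 ± 0.49 for S100A8, 1.07 ± 0.41 for CASP4, 0.99 ± 0.49 for IFNGR1, -0.94 ± 0.40 for CCND1 and -1.47 ± 0.48 for BLMH. Others shrank, to 0.93 ± 0.87 for CH25H, -0.59 ± 0.39 for CTSH and -0.30 ± 0.57 for ID3. Among late calls PTGDS and SRSF3 had probe sets that moved apart, with log2 -1.49 and 0.02 for PTGDS and 0.69 and -0.14 for SRSF3.

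The monolayer OsM array of 48 h had further differences from the mean of the monolayer controls, with no replicate. They were log2 2.08 for S100A9, 1.07 for STAT3, at least 1.67 for SOCS3, with a control at the floor, 1.17 for DSG3, -2.56 for CLDN4, -2.70 for DKK1 and -1.79 for CDC20. Of 12 arrays titled Skinethic, 1 correlated more with monolayer than with Skinethic arrays across genes.

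Cell cycle genes moved in different directions across the single sets, which have no replicates. Their median log2 ratio was -0.46 in the monolayer 1 h set, -0.43 at 4 h and 0.61 at 24 h, where 42 of 44 members were above 0, and -0.66 and -0.50 in the Skinethic sets of 48 h and 7 days. The fibroblast list had medians of 1.18 and 0.65 in the Skinethic 4 h and 48 h sets, whose OsM arrays had the raised low end, and -0.55 at 7 days.

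The log2 ratios of the Skinethic 4 h and 48 h sets correlated across genes at 0.36, against -0.07 to 0.22 for the other 27 pairs of sets. A raised low end of their OsM arrays may be the source, so the correlation was tested over the 2183 brightest genes, where a value of 0.30 or more was to count against it. It was 0.35, but 3 of the 28 pairs were then higher, up to 0.49 for the Skinethic 24 h with the 48 h set. That bound was therefore wrong, since among bright genes it no longer marks this pair. Over the 2183 dimmest genes the correlation of the 4 h and 48 h sets was 0.32, not higher than among the brightest. The other pairs were not compared among dim genes, so the question stays open.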
